A study of Homo sapiens with 2 samples.

How the data were processed

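Dual-colour Agilent whole-genome arrays measured RNA of PC3 cells plated at 40000 cells per well 24 h before transfection, grown in medium with 10% serum, and harvested 72 h after transfection with 20 nM siRNA. siGL3, named for a firefly luciferase sequence, is called a scramble control per the labels. Per the labels the 2 arrays are technical replicates with exchanged dyes, and the direction of each ratio was taken from the dyes they name. Array 2 had its sign turned, so that every ratio is siAgo1 over siGL3.

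The scanner files hold spot intensity, the mean pixel brightness of each spot and the median of its local background, made with Agilent Feature Extraction 9.5.3.1 per the file headers. They also hold a log10 ratio of Cy5 over Cy3 that Feature Extraction background-subtracted and dye-normalised, as deposited, and flags for spots that were well above background, saturated or outliers. A value table deposited by the authors holds log2 ratios of Cy5 over Cy3. Its scale is not stated in the sources used here and was inferred from the scanner ratios. It is centred near 0 with column medians of -0.002 for array 1 and 0.001 for array 2. limma is named beside Feature Extraction in the submitters' processing notes, with no parameters. Probe positions are those of hg18 as the files give them.

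Of 45015 spots per array, 43376 were not controls, and they held 41000 probes. Median signals were 303 (Cy5) and 143 (Cy3) on array 1, and 342 (Cy5) and 150 (Cy3) on array 2. limma 3.58.1 in R 4.3.3 read the files, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Signals were background-corrected with normexp (offset 50, fitted on all spots) and normalised by loess within each array with control spots at weight 0. Spots flagged as non-uniform or population outliers were left out (138 non-control spots on array 1 and 112 on array 2), and spots of 1 probe were averaged. A probe was used when it was well above background in both channels of both arrays in at least 50% of its spots, which left 23273 probes. A gene took the probe with the highest mean log2 intensity, and 4765 of the 16899 genes had 2 or more measured probes. Of the 81 counted genes, 26 had several probes, and 1, ZMIZ2, had a probe in the other direction (-0.09 against 1.16; the gene was singled out after its values were seen). Among probes with repeated spots, the median SD of the log2 ratio within a probe was 0.038 on array 1 and 0.024 on array 2, over 197 probes.

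Names were updated through a RefSeq table of a later assembly, used for names only. Of the 41000 probes, 25398 were matched by accession, 2510 by symbol, 525 by synonym and 297 through another probe of the gene with the same name, and 12270 kept the name in the file. Of the measured genes, 12107 carried a RefSeq symbol.

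With 1 replicate no test was run. Genes were counted by a size rule, a mean log2 ratio of at least 1 with both arrays in that direction by at least 0.585. Named genes were fixed by a rule before the data were examined. They are the Argonaute genes, the 12 largest and 12 smallest mean ratios among counted genes with a gene symbol, up to 4 members of each list with both arrays in 1 direction and the largest mean, and up to 6 genes per direction measured in 1 RNA only with the largest bound among those with a gene symbol. The text prints a selection of the list members. A gene that the rule selects is not reported here. Genes whose probe the files place on the Y chromosome, and XIST, are not named, but those on a list stay in its median. The 37 gene lists cover interferon response, small RNA machinery, published microRNA targets, cell cycle, stress, metabolism, adhesion, chromatin, translation and markers of other cell types. Each list's median was placed among 10000 random lists of the same size, drawn from the same 10 bins of mean intensity. A further 4 lists were added after these were seen and are used in the closing section only. For genes measured in 1 RNA only, arrays were put on one intensity scale with Aquantile after loess, and the dim RNA was set to the higher of its own signal and the lowest signal among measured probes, so these bounds are open to dye bias only as far as the dye exchange leaves it.

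On array 2, 19 spots in 1 patch (rows 86 to 92, columns 16 to 22), 18 of them not controls, had a local background over 3 times the array's median, up to 65248 in Cy3 against a median of 52.5. Array 1 had 0 such spots. normexp fits its background model on all spots, so these few reach every ratio of array 2. The planned setting was kept as the main one, and a setting in which those backgrounds were replaced by the array's median was added after the data were seen. Its value is printed where it changes a call of a named gene or list, or moves a fold by over 1.5 times, and for some SDs and dimmer probes. The authors' deposited log2 table correlates with the planned fit at 0.989 on array 2, and with the debris-replaced fit at 0.780, over 41000 probes.

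The fit was tested on simulated arrays built from the real intensities, in which 200 spots were changed by known amounts. Without debris, 99% of 100 spots with a true log2 ratio of 1.5 and 100% of 100 with 2.5 were recovered by the size rule. There were 0 false calls among the unchanged spots of the 25048 that were well above background in every channel. With the debris backgrounds on array 2, 39% and 78% were recovered, with 0 false calls, and with the backgrounds replaced 99% and 100%. The simulated noise was drawn from normal distributions, so the 0 is not the false-call rate of the real arrays. There, counting with the sign of 1 array turned gave 2 genes. Of 200 simulated random lists, 4.5% fell outside the central 95%, and 98.5% of lists shifted by 0.3 were found. These lists held 20 genes drawn at random, so a share near 5% was given by the design. Lists of genes that vary together, and shorter lists, were not simulated. The alternatives were another offset, no background correction, Agilent's own log ratio, median centring, Aquantile, other filters, flagged spots kept, averaging of probes, the authors' table, each array left out, other size rules and, for genes in 1 RNA only, saturated probes left out. The exon or untranslated region of each probe and matches of the siRNA to other transcripts were not analysed here.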

Results

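PC3 is an established line of metastatic prostate cancer cells. The cells were transfected with a small interfering RNA (siRNA) against AGO1 (siAgo1) or with the control siRNA siGL3, each at 20 nM, and total RNA was taken 72 h later. AGO1 is one of the Argonaute proteins, which hold small RNAs and act with them on target transcripts. The series asks which genes depend on AGO1 in these cells. A total of 1 siAgo1 RNA and 1 siGL3 RNA were hybridised together on 2 dual-colour Agilent arrays with the dyes exchanged, so that array 1 held siAgo1 in Cy5 and array 2 held siAgo1 in Cy3. The 2 arrays repeat the same pair of RNAs and count as 1 replicate. No test of the condition could be made and no p-value is given. Every ± below is the SD of the 2 arrays, a technical difference only. In the planned setting it also takes in the narrower ratios of array 2, so it is not repeat error alone. Of the non-control spots, 61.4% (siAgo1) and 62.4% (siGL3) were well above background on array 1, and 59.6% (siAgo1) and 60.9% (siGL3) on array 2. The number of arrays limits the precision.

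AGO1 itself was lower in siAgo1 on both arrays, by 1.80-fold in the mean, with a log2 ratio of -0.85 ± 0.27. Array 1 gave -1.04 and array 2 gave -0.66. The probe lies on chromosome 1 at 36162281 to 36162340 (hg18, as the array files give it) and carries the accession NM_012199. Its exon or untranslated region was not analysed here. A second AGO1 probe was not well above background in any channel and gives no level. AGO1 stood below its control on both arrays and short of 2-fold in the mean. It was past 2-fold without background correction, at -1.12 ± 0.11, and with Agilent's own log ratio, at -1.18 ± 0.15. The log2 ratio was -1.13 ± 0.12, or 2.18-fold lower, when 19 spots of array 2 with very high local background were given the array's median background, a setting chosen after the data were seen and called debris-replaced below. In the planned setting the other Argonaute genes had log2 ratios of 0.01 ± 0.08 for AGO2, 0.05 ± 0.05 for AGO3 and -0.25 ± 0.32 for AGO4. The AGO4 ratio was smaller than the SD of its arrays there, and larger debris-replaced, at -0.33 ± 0.21.

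Across 16899 measured genes, the haem-degrading enzyme HMOX1 and a set of interferon-induced genes were far higher in siAgo1, and lists of ATF4 and amino acid stress, cholesterol synthesis, and hypoxia and glycolysis genes had medians below 0. A gene was counted when its mean ratio was at least 2-fold and both arrays went the same way by at least 1.5-fold each. By this rule 45 genes were higher in siAgo1 and 36 were lower. Counting with the sign of 1 array turned, which leaves only dye bias and noise, gave 2 genes. The counts were 175 higher and 95 lower in the debris-replaced setting, which held all 45 and all 36 of the first counts, and the turned count was then 5. Array 1 alone gave 320 higher and 310 lower at 2-fold, and array 2 alone gave 38 and 30.

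Among the higher genes, HMOX1 stood first at 11.5-fold (log2 ratio 3.53 ± 0.19). IFIT2 followed at 6.03-fold (2.59 ± 0.50), GDF15, a stress-responsive cytokine, at 5.00-fold (2.32 ± 0.22), and IFIT1 at 3.72-fold (1.89 ± 0.43). The cell surface genes LYPD3 (1.86 ± 0.73) and TSPAN8 (1.80 ± 0.49) came next, then OASL (1.61 ± 0.45), PSORS1C1 (1.61 ± 0.74) and ARF4 (1.57 ± 0.15), a GTPase of Golgi traffic. The histone gene H2AC6 (1.54 ± 0.97), ULK1 (1.53 ± 0.05), the kinase that starts autophagy, and the neurofilament gene NEFL (1.52 ± 0.16) closed the 12 largest. The HMOX1 probe lies on chromosome 22 at 34120122 to 34120181 and the GDF15 probe on chromosome 19 at 18360890 to 18360949 (hg18). Dimmer probes of the same gene gave smaller ratios in the same direction, with 1.05 for IFIT2, 0.57 for LYPD3, 0.48 for PSORS1C1, 0.71 for NEFL and 1.22 for ULK1. A second H2AC6 probe, well above background in only 1 of the 4 channels, was at 0.20. The H2AC6 probe that was used took its name through another probe of the gene. Debris-replaced, the dimmer probes of IFIT2 and LYPD3 were at 1.68 and 1.25. In that setting the arrays came close for LYPD3 (2.38 ± 0.01), PSORS1C1 (2.15 ± 0.04) and OASL (1.90 ± 0.04). H2AC6 kept a wider SD (1.87 ± 0.50), and that of GDF15 did not fall (2.34 ± 0.25).

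Among the lower genes, FGFBP1, which encodes a carrier protein of fibroblast growth factors, stood first at 3.76-fold lower (log2 ratio -1.91 ± 0.22). Asparagine synthetase ASNS (-1.80 ± 0.18) and the mTOR inhibitor DDIT4 (-1.78 ± 0.15) followed, then the fatty acid desaturase SCD (-1.64 ± 0.57). The matrix protein gene SPARC was at -1.60 ± 1.24, with its arrays far apart at -2.48 and -0.72, and at -2.70 ± 0.30 in the debris-replaced setting. CTNNB1, the gene of beta-catenin, was at -1.53 ± 0.71. The sterol genes IDI1 (-1.43 ± 0.42) and INSIG1 (-1.39 ± 0.42), the disulphide isomerase gene PDIA6 (-1.35 ± 0.65), the amino acid transporter SLC7A5 (-1.35 ± 0.15), the mitochondrial folate enzyme MTHFD2 (-1.33 ± 0.14) and IGFBP3 (-1.25 ± 0.72) completed the 12. The probes of CTNNB1 disagreed in size, at -1.53, -0.75 and -0.14, as did those of SCD, at -1.64, -1.14, -0.78 and -0.38, and of SLC7A5, at -1.35 and -0.52. Debris-replaced, the same probes were at -1.65, -1.10 and -0.41 for CTNNB1 and at -1.74, -1.40, -0.86 and -0.64 for SCD. Those of SLC7A5 were then at -1.42 and -0.89, so part of the disagreement of these probes went with the debris backgrounds and part remained. A second IGFBP3 probe, well above background in 3 of the 4 channels, was at -0.65, and at -1.055 debris-replaced. In that setting the arrays came close for IGFBP3 (-1.73 ± 0.04) and INSIG1 (-1.72 ± 0.04), but not for PDIA6 (-1.38 ± 0.61) or CTNNB1 (-1.65 ± 0.54). The FGFBP1 probe lies on chromosome 4 at 15546430 to 15546489 and the ASNS probe on chromosome 7 at 97319397 to 97319456 (hg18).

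**Figure D1:**
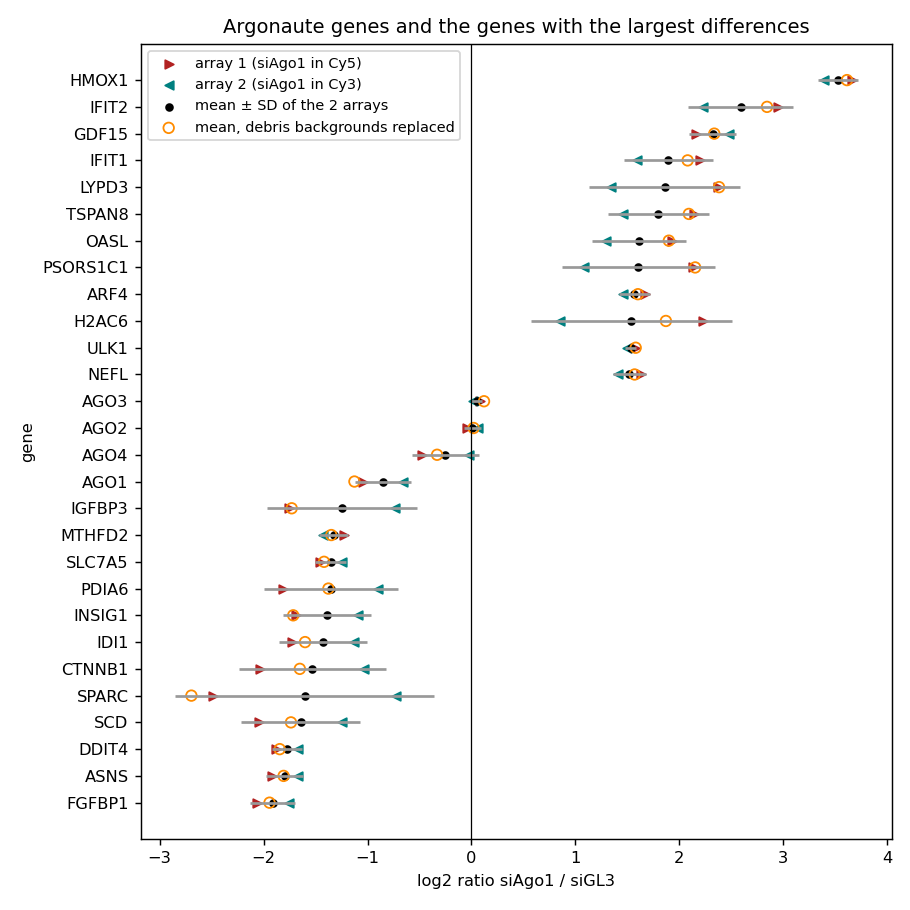
Log2 ratio of siAgo1 over siGL3 (horizontal axis) for the Argonaute genes and the 12 genes highest and 12 lowest by the size rule, with each array as a triangle, the mean as a black point, the SD of the 2 arrays as a bar and the debris-replaced mean as an open circle. HMOX1 lies at 3.53 and FGFBP1 at -1.91, AGO1 at -0.85, and AGO2 and AGO3 lie near 0.

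Gene lists fixed before the data were examined were described by the median log2 ratio of their measured members, and by its percentile among 10000 random lists of the same size and brightness. Of the 37 lists, 11 had a median in the outer 5% of their random lists. The interferon response list stood furthest from 0. Its median was 1.02, at percentile 100, with 19 of 25 members measured. Of these 19, 8 were at least 2-fold higher and 18 were at least 1.5-fold higher in the mean with both arrays in that direction, and none was lower. IFIT2, IFIT1 and OASL are given above, and IFI27 was at 1.30 ± 1.18, short of the rule on array 2. The median was 1.5 on array 1 and 0.52 on array 2. In the debris-replaced setting it was 1.38, 14 members were at least 2-fold higher, and IFI27 met the rule at 1.99 ± 0.20.

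Metabolic lists were lower in siAgo1. The list of ATF4 and amino acid stress genes had a median of -0.55 (percentile 0), or -0.86 on array 1 and -0.36 on array 2, with 4 of 19 members at least 2-fold lower and 9 at least 1.5-fold lower. ASNS, DDIT4 and SLC7A5 led it, with PHGDH, the first enzyme of serine synthesis, at -1.02 ± 0.33. Cholesterol synthesis had a median of -0.63 (percentile 0), or -0.73 on array 1 and -0.29 on array 2, with 11 of 21 members at least 1.5-fold lower. Besides IDI1 and INSIG1, squalene synthase FDFT1 was at -0.91 ± 0.02, and MSMO1 was at -0.91 ± 0.98 and at -1.47 ± 0.18 in the debris-replaced setting, where it met the rule. Hypoxia and glycolysis genes had a median of -0.60 (percentile 0), or -0.64 on array 1 and -0.38 on array 2, with 11 of 22 members at least 1.5-fold lower, among them phosphoglycerate kinase PGK1 (-1.16 ± 0.25), the pyruvate dehydrogenase kinase PDK1 (-1.01 ± 0.09) and enolase ENO1 (-0.91 ± 0.50). CA9, a carbonic anhydrase, was at -0.97 ± 1.08, and at -1.59 debris-replaced. Fatty acid synthesis and storage had a smaller median of -0.31 (percentile 0.1), or -0.36 on array 1 and -0.14 on array 2, with SCD at the front, citrate lyase ACLY at -0.90 ± 0.26 (-1.03 and past the rule debris-replaced) and FASN at -0.56 ± 0.69. Oxidative phosphorylation was at -0.10 (percentile 7.8), with none of 24 members past 1.5-fold.

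Genes of mitosis were lower and genes of DNA replication were near level. The G2/M list had a median of -0.50 (percentile 0), and 6 of 26 members were at least 1.5-fold lower. NUSAP1 was at -1.06 ± 0.72 (-1.25 and past the rule debris-replaced), TPX2 at -0.70 ± 0.07, HMMR at -0.69 ± 0.12 and KIF20A at -0.68 ± 0.24. The G1/S and replication list had a median of -0.06 (percentile 20.0), with RRM2 at -0.72 ± 0.16 and CCNE1 at 0.48 ± 0.19. The p53 target list had a median of 0.04 (percentile 64.0), and 0.12 (percentile 88.1) debris-replaced. GDF15 met the 2-fold rule, and TP53INP1 (1.01 ± 1.12) and CDKN1A (1.01 ± 1.01), the cell cycle inhibitor p21, met it in the debris-replaced setting at 1.82 and 1.55. Apoptosis regulators of the BCL2 family had a median of 0.01 (percentile 52.6), with BCL2A1 at 0.70 ± 0.15. Replication-dependent histones had a median of 0.18 (percentile 95.6), with H2AC6 highest and the linker histone H1-2 at -0.78 ± 0.12. The histone median was 0.39 on array 1 and -0.05 on array 2.

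Smaller shifts appeared in stress, adhesion and matrix lists. Heat shock proteins had a median of 0.26 (percentile 99.6), with HSPA8 at 0.88 ± 0.34, HSPH1 at 0.65 ± 0.04 and HSP90AA1 at -0.48 ± 0.08. The median was 0.41 on array 1 and 0.05 on array 2, and turned to -0.028 when all measured probes of a gene were averaged. Metallothioneins had a median of 0.29 (percentile 98.1) over 7 genes, or 0.40 on array 1 and 0.15 on array 2, led by MT1B at 0.37 ± 0.20. Endoplasmic reticulum chaperones had a median of 0.16 (percentile 95.3), with PDIA6 lower and DNAJB9 at 0.66 ± 0.33. Epithelial junction and keratin genes had a median of 0.16 (percentile 97.9) and 0.35 debris-replaced, with EPCAM at 0.86 ± 0.30, and CLDN1 at 0.79 ± 0.92 and 1.39 debris-replaced. Invasion and matrix remodelling had a median of 0.17 (percentile 99.3), or 0.14 on array 1 and 0.06 on array 2, with the integrin ITGA2 at 1.13 ± 0.96, and past the rule debris-replaced at 1.36. Mesenchymal genes had a median of 0.02 (percentile 59.0), with SPARC lower and S100A4 at 0.70 ± 0.08. TGF-beta and YAP target genes had a median of -0.24 (percentile 0.1), or -0.38 on array 1 and -0.04 on array 2, with CCN2 at -0.78 ± 0.03, TGFB2 at -0.78 ± 0.20, INHBA at -0.84 ± 0.15 (-1.21 and past the rule debris-replaced) and AMOTL2 in the other direction at 1.08 ± 0.20. NF-kB targets were mixed, with a median of 0.04 (percentile 62.0) that turned to -0.05 debris-replaced, TNFAIP2 at 0.89 ± 0.60 (1.38 and past the rule debris-replaced) and IL1B at -0.80 ± 0.06. Immediate early genes had a median of -0.13 (percentile 8.7), with SPRY4 at -0.59 ± 0.37 and MYC at -0.43 ± 0.30.

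Lists tied to small RNA action lay within their random lists. Argonaute and small RNA machinery genes had a median of -0.02 (percentile 35.2) over 19 genes, and 0.02 debris-replaced. After AGO1 the largest ratio was that of DICER1, the RNase that cuts small RNA precursors, at -0.48 ± 0.02. Published microRNA targets had medians of 0.03 for let-7 (percentile 65.3), -0.02 for miR-21 (41.8), -0.10 for the miR-17 family (21.4), -0.14 for miR-29 (5.4), 0.04 for miR-221 and miR-222 (60.5) and 0.12 for miR-200 (80.6). The miR-17 median was -0.21 (percentile 5.0) debris-replaced, and that of miR-21 turned to 0.01. The let-7 target ARID3B was 2-fold higher at 1.21 ± 0.32, and TGFBR2, on the miR-21 and miR-17 lists, was at -0.66 ± 0.02. Polycomb and heterochromatin genes had a median of -0.01 (percentile 42.0), with BMI1 at 0.59 ± 0.08, and splicing factors had a median near 0 (percentile 47.4), with PTBP2 at -0.58 ± 0.15. MYC and ribosome biogenesis genes had a median of 0.13 (percentile 95.5), and 0.24 (percentile 99.8) debris-replaced, with RRS1 at 0.77 ± 0.26. Cytosolic ribosomal proteins had a median of 0.03 (percentile 67.7), with 0.24 on array 1 and -0.23 on array 2.

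Markers of other cell types gave no shift past their random lists, and few of them were measured. Medians were 0.05 for luminal prostate and androgen response genes (10 of 17 measured, percentile 67.1), 0.14 for basal prostate markers (6 of 10, percentile 90.7) and 0.06 for neuroendocrine markers (6 of 12, percentile 66.7). They were 0.02 for leukocyte markers (3 of 12, percentile 54.9), near 0 for fibroblast markers (2 of 10, percentile 48.8) and -0.03 for endothelial markers (3 of 9, percentile 31.0). Among the 3 leukocyte matches is NDUFA2, matched through a shared name and not a leukocyte marker. The others were CD79A at 0.42 ± 0.33 and CD68 at -0.54 ± 0.36, so the median of 0.02 is NDUFA2's own ratio and describes no leukocyte gene. Among the 6 neuroendocrine matches is MEN1, which is also not on the list as fixed, so that count and median include it. The largest single ratios were -0.82 ± 0.80 for ENO2, which was past the rule debris-replaced at -1.02, and 0.74 ± 0.50 for the luminal transporter SLC45A3.

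**Figure D2:**
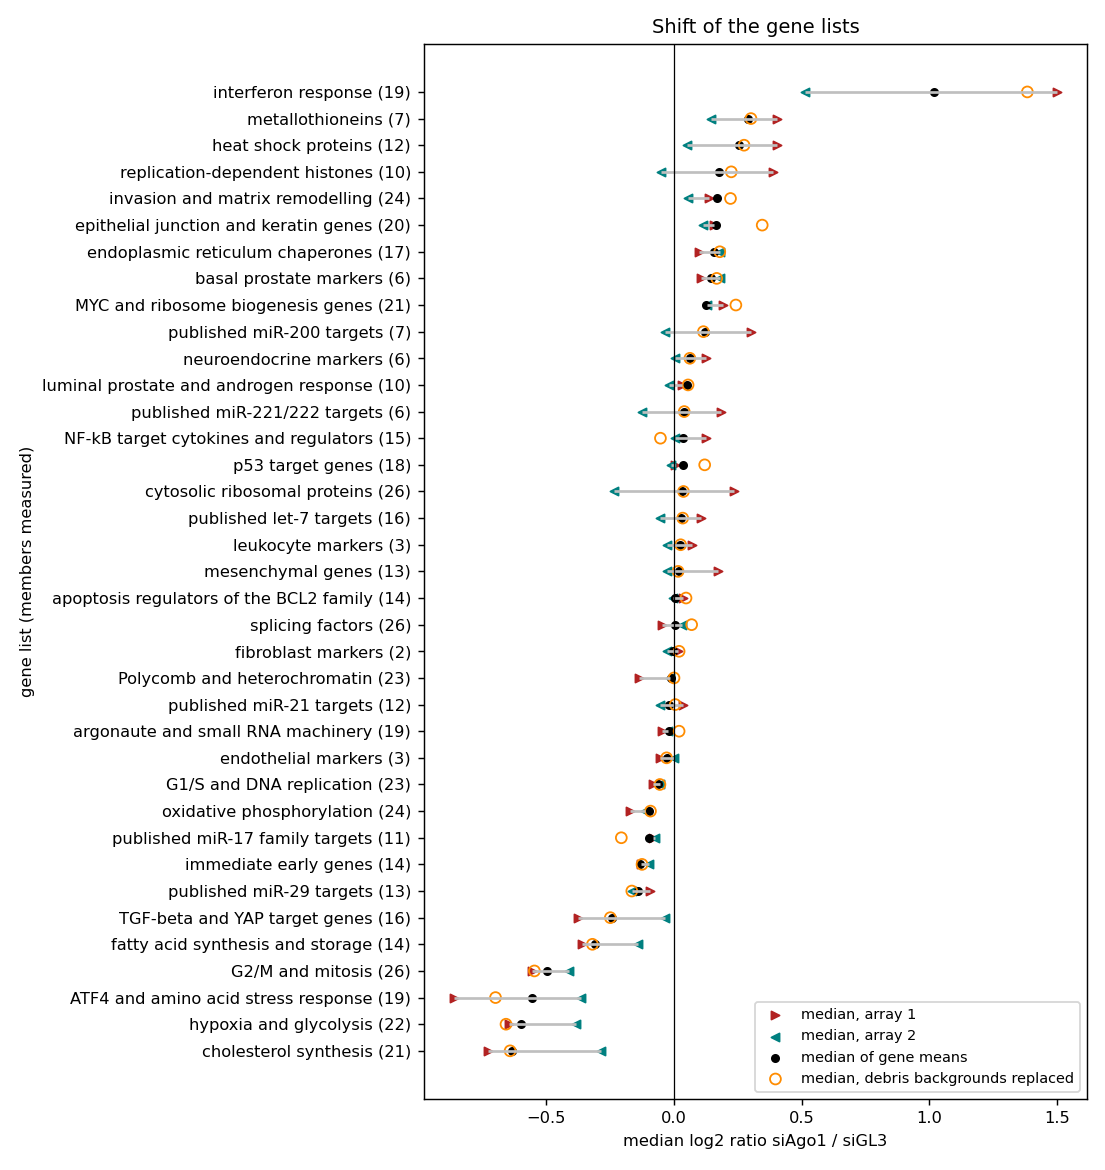
Median log2 ratio of siAgo1 over siGL3 (horizontal axis) for each of the 37 gene lists, with the number of measured members in brackets, the medians of array 1 and array 2 as triangles, the median of gene means as a black point and the debris-replaced median as an open circle. Interferon response lies alone at 1.02, and cholesterol synthesis, hypoxia and glycolysis, ATF4 and G2/M lists lie between -0.63 and -0.50. The leukocyte and neuroendocrine lists each include a gene matched through a shared name that is not on the list as fixed.

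A further 300 genes were well above background in 1 of the 2 RNAs on both arrays, with every probe of the other RNA not well above background. For these the fold is a lower bound, set against the higher of the dim signal itself and the lowest signal of a measured probe. Of them, 117 were measured in siAgo1, all with a bound above 1, and 183 in siGL3, 171 of them with a bound above 1. A bound above 1 is nearly given by choosing genes detected in 1 RNA only. No count with a turned sign was made for these genes. The share of spots well above background was higher in siGL3 on both arrays, so nothing is read from the larger siGL3 count. Of those with a gene symbol, the ones with the largest bounds are named. Among the siAgo1 genes, TMEM140 was at least 1.87-fold higher and RSAD2, an interferon-induced antiviral gene, at least 1.77-fold higher, and the debris-replaced bounds were 3.43 and 2.69. TRIM63, a muscle ubiquitin ligase, was at least 1.67-fold higher, THSD7A at least 1.58-fold, BEX2 at least 1.57-fold and AADAC at least 1.55-fold. Among the siGL3 genes, the sodium channel subunit SCNN1G was at least 1.67-fold higher in siGL3 (2.60-fold debris-replaced), and the mucin MUC13 at least 1.24-fold. The bounds were 1.23 for C1QL1, 1.20 for MAP1A, 1.19 for FAM107A and 1.19 for TSPAN7. All of these signals were near the floor.

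Across genes, which are not independent replicates, the log2 ratios of the 2 arrays correlated with Pearson's r of 0.45 and Spearman's rho of 0.43, and with 0.55 and 0.48 debris-replaced. Their SD across genes was 0.46 on array 1 and 0.23 on array 2, and 0.37 on array 2 debris-replaced.

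**Figure D3:**
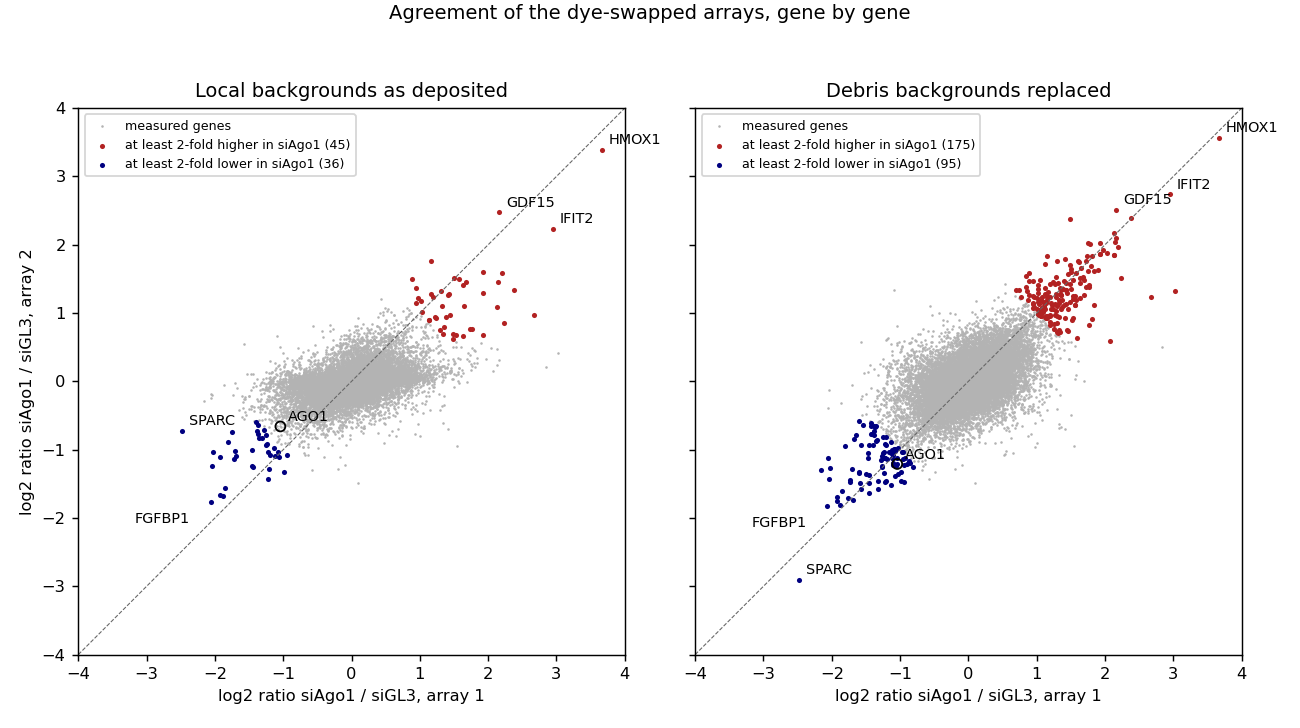
Log2 ratio of siAgo1 over siGL3 on array 1 (horizontal axis) against array 2 (vertical axis) for 16899 genes, with local backgrounds as deposited on the left and debris backgrounds replaced on the right. Red points are genes at least 2-fold higher and blue points genes at least 2-fold lower by the size rule, the open circle is AGO1, and the dashed line marks equal ratios. The cloud is flatter on the left, where the SD on array 2 is 0.23 against 0.46 on array 1.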

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

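One signal lay in data outside the comparisons. All 320 spike-in control spots (RNAs added to both samples at labelling) were well above background in every channel of both arrays, while 3 and 4 of 153 negative control spots were on array 1 (Cy5 and Cy3) and 2 and 2 on array 2. Their median signal was 17676 in Cy5 and 4324 in Cy3 on array 1, and 17404 and 4147 on array 2. The amounts added are not given in the sources used here, so no ratio was read from them.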

How the results depend on the processing

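The debris-replaced setting was chosen after the data were seen, and all others before. With 2 technical arrays and 1 pair of extracts, nothing here bears on spread between cultures, and signal over background limits the dim genes. AGO1 was lower under every setting. Its log2 ratio was -1.18 with Agilent's processed log ratio, -1.13 debris-replaced and -1.12 without background correction. Under the other settings of both arrays it stayed within the SD of its arrays and short of 2-fold, and each array alone gave -1.04 and -0.66. With 1 measured AGO1 probe, the other filters, flagged spots kept and probe averaging returned the planned value and add nothing. Offset 0 (-0.88) and median centring (-0.80) keep the debris backgrounds. The authors' table (-0.84) correlates at 0.989 with the planned fit on array 2. These settings thus do not bear on whether AGO1 fell short of 2-fold. Genes higher and lower were 157 and 91 without background correction, 347 and 186 with Agilent's log ratio, 17 and 20 with median centring in place of loess, and 175 and 95 debris-replaced. With each array required to reach 2-fold they were 23 and 19, and with a mean of 1.5-fold and both arrays in 1 direction 422 and 443. A 2-fold mean alone gave 68 higher, and the lower count stayed within 1.5 times the main one. Single arrays gave 38 to 320 higher and 30 to 310 lower. Genes measured in 1 RNA only numbered 860 and 1016 on single arrays, since 1 array need not be borne out by the other. The correlation between arrays was 0.42 with offset 0, 0.55 without background correction, 0.56 with Agilent's log ratio, -0.16 with median centring, 0.44 with the filter in 1 RNA, 0.43 with no filter, 0.43 with flagged spots kept, 0.45 with probes averaged, 0.45 in the authors' table and 0.55 debris-replaced. Without loess the dye bias stays in each ratio and turns sign with the dyes. The debris-replaced setting differs from the planned one in the debris backgrounds alone, so its differences come from them. Leaving out background correction also keeps them out, and gave values near the debris-replaced ones. Whether the debris accounts for that likeness, and the cause of the other differences, was not tested. Aquantile acts on intensities and left every ratio as it was, so it says nothing about stability. Of the 37 list medians, 8 moved by more than the SD of their array medians debris-replaced, 13 with Agilent's log ratio and 12 with median centring. The heat shock median reversed, to -0.028, with probes averaged, and no other list past its random lists and no counted named gene changed direction across both-array settings. No paired analysis was possible because the result comes from no test.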

Other observations

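Of the tests below, those of NRF2 targets, antigen presentation, autophagy and the graft of debris backgrounds were set before their results were seen, and the others after.

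Gene groups outside the first lists were examined after those lists had been seen. Cytosolic aminoacyl-tRNA synthetases, many of which are ATF4 targets, were lower in siAgo1, with a median log2 ratio of -0.29 at percentile 0 of random lists, or -0.36 on array 1 and -0.10 on array 2. Of 20 measured members, 4 were at least 1.5-fold lower, AARS1 (-0.96 ± 0.56), YARS1 (-0.93 ± 0.70), CARS1 (-0.76 ± 0.54) and GARS1 (-0.59 ± 0.25), and AARS1 (-1.003) and YARS1 (-1.04) met the 2-fold rule debris-replaced. The synthetase median thus went the same way as that of the ATF4 list, in which 9 of 19 members were at least 1.5-fold lower. Debris-replaced, 10 members of the ATF4 list were at least 1.5-fold lower and 1 at least 1.5-fold higher. AARS1 and YARS1 had been seen before the synthetase list was drawn up, so it is no independent support. Whether the ATF4 programme as a whole was lower stays open. NRF2 target genes did not go with HMOX1. Their median was -0.15 at percentile 2.1, or -0.08 on array 1 and -0.02 on array 2, with TXNRD1 at -0.90 ± 0.92 and AKR1C3 at 0.64 ± 0.28, which argues against NRF2 targets being raised together behind the HMOX1 ratio of 3.53. Antigen processing and presentation genes had a median of -0.07 at percentile 22.6, with PSME1 at -0.45 ± 0.21 and PSMB10 at 0.38 ± 0.01, so the high interferon-induced genes were not joined by this group. Autophagy genes other than ULK1 had a median of 0.16 at percentile 96.6, between the bounds set for a shared shift and for none, and at percentile 94.4 debris-replaced, which meets the bound for none. Since the reading changes with the setting, whether they go with ULK1 stays open.

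The log2 ratios of array 2 were narrower than those of array 1, with an SD of 0.23 against 0.46. Weaker signal is argued against, since median signal on array 2 was 1.05 times that of array 1 in the channel with the lower ratio. Putting the debris backgrounds of array 2 on the same spots of array 1 brought the SD of array 1 to 0.584 of its value, which is consistent with those few backgrounds narrowing the ratios through the background fit. They are not the whole account, because with them replaced the SD of array 2 was still 0.80 of that of array 1. No biological explanation was tested, since both arrays hold the same RNAs.

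Interferon-induced genes were higher in siAgo1. Dye bias is argued against by a list median above 0 on both arrays, the lower being 0.52, and debris by a median of 1.38 with those backgrounds replaced. Whether this follows the loss of AGO1, the siAgo1 duplex itself or a chance difference between cultures cannot be told apart, because 1 pair of extracts and 1 siRNA against AGO1 were compared. Loss of AGO1 stays an open and untested explanation.

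ATF4, cholesterol and glycolysis genes were lower in siAgo1. Over the 62 measured members the median was -0.75 on array 1 and -0.36 on array 2, which argues against dye bias. Less endoplasmic reticulum stress may underlie the ATF4 part. The chaperone list had a median of 0.16 at percentile 95.3, which meets the bound set against this explanation. Its members went both ways, with 10 above 0 and 7 below, so the list decides nothing. A difference in cell density or medium use between wells could lower all 3 lists and cannot be told apart from the knockdown with 1 pair of extracts. An effect of AGO1 loss stays open and untested.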
